A study of Zea mays with 11 samples.

How the data were processed

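Anthers of *Zea mays* at prophase I of meiosis were profiled with 2 assays. RNA-seq covered 3 libraries of the wild-type inbred line A344 and 3 of the *pam1* mutant, and native RNA immunoprecipitation (RIP), in which an antibody pulls down a protein with the RNA bound to it, covered 3 anti-PAM1 and 2 IgG samples from A344. Per the labels' protocols, RNA was extracted with a NucleoSpin kit and the RNA-seq libraries were built from total RNA with a directional NEBNext Ultra II kit. Groups and replicate numbers came from the sample titles. The columns of the count table were matched to the samples by name, with the mutant's columns headed PAML. Nothing in the labels says whether replicates were separate plants, so p-values measure the spread between these samples, which may be partly technical.

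The deposited count table holds whole-number counts per row, not normalized, for 44474 rows and 6 libraries. STAR, DESeq2, MACS2 and Bowtie2 2.4.5 are named in the submitters' processing notes, without roles. The program that made the counts, its strand setting and its treatment of reads that match several places are not given in the sources used here. Reads of near-identical copies or of overlapping genes may therefore be divided between rows in an unknown way.

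The authors' deposited table compares A344 with *pam1*. It holds a mean signal per row (counts divided by size factors), a log2 fold change with its standard error, a Wald score, and raw and adjusted p-values, per the file headers. Its log2 values are positive where A344 was higher, the reverse of the order in its name. A DESeq2 1.42.0 fit with default settings gave the same log2 values with the opposite sign, within 0.001, for 36964 of 36964 rows. That tolerance was set after a much tighter one, tried first, had matched fewer rows.

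The RIP data are a single deposited peak list in which the samples were combined. For each peak the authors' file gives a fold enrichment, −log10 p and −log10 q values and a score that equals 10 times the −log10 q value for all 711 peaks, in whole numbers. The contig names in the list are those of the B73 v4 assembly, and positions are given here on that assembly, counted from 1. The name of the list sets the antibody against IgG and carries short tags that may stand for quality and false discovery limits. The caller's settings are not otherwise given in the sources used here. The lowest −log10 q in the list was 1.36. No value per sample is in the list, so replicate spread could not be computed for any peak.

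Names came from the count table itself and from a gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names and neighbour order only. Of the rows, 44146 carry Zm00001d identifiers, 154 are microRNA (miRNA) genes and 174 carry GRMZM identifiers. A symbol was matched for 153 rows, all of them miRNA rows. The files do not pair Zm00001d identifiers with gene names. The row of *pam1* itself was therefore not looked at, and the mutant labels were not checked against it. For the same reason none of the 20 gene lists fixed before the data were examined (meiotic axis and synapsis, recombination, CCR4-NOT and deadenylation, decapping, Mei2-like proteins, nuclear envelope and telomere, anther regulators, tapetum secretion, phasiRNA pathway, heat shock, ribosomal proteins, histones, cell cycle, replication, photosynthesis, pollen, defence, cell wall, flavonoids and MADS-box genes) reached 3 matched members: 0 members were matched and none was tested. Peaks were not assigned to genes, and the tests of peak genes against changed genes and of 10 Mb windows were not run.

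Rows were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, default filterByExpr, quasi-likelihood test, two-sided), as *pam1* minus A344, with Benjamini-Hochberg adjusted p under 0.05. This left 18491 tested rows. CPM are the counts scaled to a common library total. The CPM means and SDs given for rows are on the total counts of each library, without TMM factors. Sets of rows were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, on log2 CPM with a prior count of 2. Camera compares a set with the other rows, while fry asks only whether the set's own rows change. Ratios of summed counts carry exact conditional 95% intervals. These intervals and the floor of 3 counts over a group, used where a group had no count, cover counting error only. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

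Library totals were 1918457 to 2595247 counts, with a median of 58 counts per library for a tested row. A single table was simulated with the same means and library sizes and a common dispersion for all rows. In it, the edgeR step on 18116 rows recovered 78% of 100 rows changed 2-fold and 96% of 100 rows changed 4-fold. There were 16 false calls. Real rows differ in dispersion, so these rates may not hold for them. No pair of libraries was a duplicate: within groups, chi-square per degree of freedom over rows was 1.99 to 5.42. It was 1.99 to 2.27 among *pam1* libraries and 3.22 to 5.42 among A344 libraries, so the A344 replicates differed more. The highest, A344 replicates 1 and 2, was above the 4.69 of *pam1* replicate 3 with A344 replicate 3.

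Whether the replicate numbers pair the samples is not settled. After removing group means, same-numbered libraries correlated at 0.134, 0.118 and 0.128 across rows, and each library correlated best with its own number. Removing the means forces positive and negative values to balance between the groups, and the match was not tested. The labels name no shared batch or day. A fit with the replicate number as a block was run beside the main one.

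The rule fixed beforehand named the called rows with a symbol and the largest changes, at most 2 unnamed identifiers in each direction, and up to 4 rows near 0 in 1 group. MIR159g (no symbol matched), MIR159k, MIR167g, MIR398a, the grouping of miRNA rows by family, GRMZM rows as a set, windows of 200 tested rows in table order, the limits for rows near 0 and the measurements on *pam1* replicate 3 were chosen after the data were seen. Table order was used because the rows form 10 stretches: 152 of 153 miRNA rows within them lie on their stretch's own chromosome in the reference table, and 142 of 142 adjacent miRNA pairs follow reference order. Each window was tested for an excess of changed rows with a one-sided Fisher's exact test, adjusted over 92 windows. In 100 simulated tables with calls at random positions, 0 had a window past the threshold, and a planted window was found.

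Alternatives were DESeq2 size factors, library size alone, no low-count filter, a filter of 1 CPM in 3 libraries, limma voom, DESeq2, the replicate block, adjusted p under 0.01, an absolute log2 fold change of at least 1, leaving out each library, and stricter peak thresholds.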

Results

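PAM1 (plural abnormalities of meiosis) is a maize protein with an RNA recognition motif, and *pam1* mutants are disturbed in male meiosis. The RNA-seq part of the study asked how the anther transcriptome of the mutant differs from that of the wild type, and the RIP part asked which RNAs the motif binds. Anthers at prophase I were collected from the inbred line A344 (3 libraries) and from *pam1* plants (3 libraries). Total counts were 2034996, 2595247 and 2002784 in *pam1* replicates 1 to 3, and 2420973, 1918457 and 2270102 in A344 replicates 1 to 3. The first principal component of log2 CPM held 65.3% of the variance and separated the groups, with *pam1* replicates at 52.4, 47.8 and 35.4 and A344 replicates at −48.0, −46.1 and −41.5. The second held 12.7% and set A344 replicate 1 (33.6) apart from A344 replicate 2 (−33.4). A344 replicate 3 lay at 0.65 on it and the *pam1* replicates at 9.94, −2.85 and −7.95.

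In *pam1* anthers, 2748 of 18491 tested rows changed (14.9%), of which 1513 were higher and 1235 lower than in A344. The changes were mostly moderate, with a median of 1.99-fold among the changed rows, but 187 rows rose and 83 fell by at least 3 on the log2 scale. Among the genes that the count table names, 5 miRNA genes rose and none fell. The largest of these changes was in MIR2275c, a gene for the miRNA family that triggers phased small RNAs in grass anthers, at 11.3 ± 3.16 CPM in *pam1* and 0.285 ± 0.247 CPM in A344 (SD, n = 3 each). More rows had signal in the mutant: at an equal depth of 1918457 counts, 30098 ± 429.9 rows had a count in *pam1* and 27437 ± 1186 in A344 (SD, n = 3 each; exact permutation test, two-sided p = 0.1, and 0.25 with signs flipped within replicate numbers, each the smallest that test allows). Whether sequence differences between the lines or loss of PAM1 gave this was not tested.

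The calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Groups did not overlap in 5776 tested rows (31.2%, against 10% by chance), and 2705 of the changed rows were among them. The median log2 fold change of all tested rows was −0.01, and 0.02 with library size alone. TMM scaling centres most rows near 0, so the first value cannot show whether there was an overall shift. Without *pam1* replicate 1 the number of changed rows was 1768, and the number of lower rows was 728 without that library and 723 without *pam1* replicate 2.

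**Figure D1:**
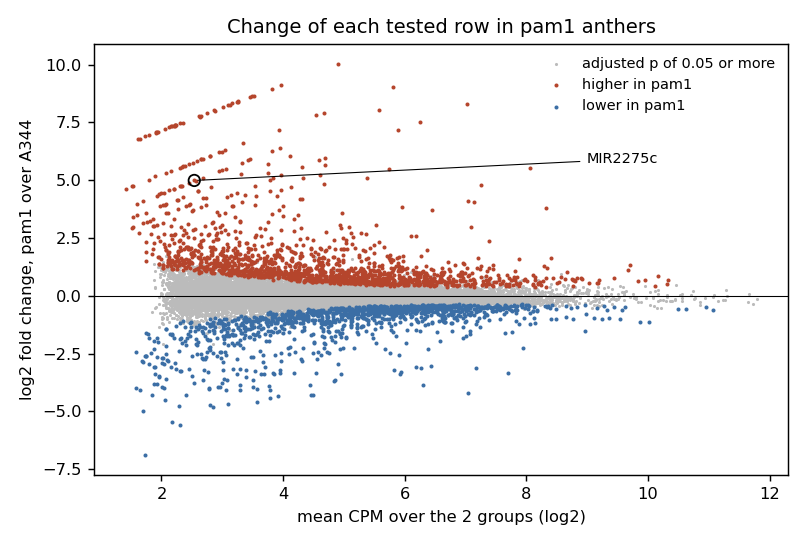
Log2 fold change (*pam1* over A344) of each tested row against the log2 of its mean CPM over both groups. Red points are the 1513 rows higher in *pam1*, blue points the 1235 lower ones and grey points the rows that did not pass the test; the ring marks MIR2275c at 4.99.

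The largest changes in both directions were in rows with no gene name. Zm00001d004085 had 406 counts in the 3 *pam1* libraries and 0 in A344, and stood at 59.7 ± 25.6 CPM in *pam1* (SD, n = 3). This was 135-fold higher than a floor of 3 counts over the A344 group (edgeR adjusted p = 1.73e-05). The lower 95% limit of its ratio was 109. Zm00001d036420 had 208 counts against 0, at 31.2 ± 4.55 CPM (SD, n = 3), 69.1-fold higher by the same floor (edgeR adjusted p = 2.20e-06). The lower 95% limit of its ratio was 55.7. In the other direction, Zm00001d010482 had 0 counts in *pam1* and 44 in A344, at 6.61 ± 1.10 CPM in A344 (SD, n = 3). This was 14.7-fold lower in *pam1* by a floor of 3 counts over that group (edgeR adjusted p = 0.000238). The upper 95% limit of its ratio was 0.0871. Zm00001d020479 had 1 count in *pam1* and 64 in A344, a ratio of 0.0156 with a 95% interval of 0.000388 to 0.0899 (log2 fold change −5.57, edgeR adjusted p = 6.30e-05). Its only *pam1* count was in replicate 3, and its fitted log2 fold change was −7.46 without that library and −4.93 with limma voom.

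Of the 154 miRNA genes in the table, 7 had enough counts to be tested. Besides MIR2275c (log2 fold change 4.99 ± 0.57 SE, edgeR adjusted p = 6.30e-05), MIR528a rose from 2.37 ± 0.706 to 8.82 ± 1.59 CPM (SD, n = 3 each; log2 1.83 ± 0.36 SE, edgeR adjusted p = 0.00369). MIR159g rose from 3.76 ± 0.945 to 12.9 ± 1.88 CPM (log2 1.74 ± 0.31 SE, edgeR adjusted p = 0.00167). MIR159b rose from 3.70 ± 0.994 to 10.4 ± 3.15 CPM (log2 1.43 ± 0.35 SE, edgeR adjusted p = 0.0132), and MIR408b from 4.34 ± 3.08 to 12.2 ± 2.83 CPM (log2 1.43 ± 0.39 SE, edgeR adjusted p = 0.0243). MIR159k, at 18.0 ± 4.12 CPM in *pam1* and 9.05 ± 6.22 CPM in A344, did not pass the test (log2 0.90 ± 0.39 SE, edgeR adjusted p = 0.153) but did with the replicate number as a block (log2 1.01, adjusted p = 0.0291) and with no low-count filter (adjusted p = 0.0128), in a range of 0.0128 to 0.382 over its alternatives. Its log2 value ranged from 0.48 (without A344 replicate 2) to 1.33 (without A344 replicate 1). MIR167g, at 7.48 ± 0.559 CPM in *pam1* and 7.12 ± 1.94 CPM in A344, had a log2 fold change of 0.04 ± 0.30 SE (edgeR adjusted p = 0.956). As background, miR159 targets MYB transcription factors of the GAMYB type, which act in anthers, and miR408 and miR528 target mRNAs of copper proteins.

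Adjusted over the list alone, 6 of the 7 miRNA genes were higher. Their median log2 fold change was 1.43, and camera placed the set above the other rows with an adjusted p of 1.95e-05. That call was lost with an estimated correlation (adjusted p = 0.211 with an estimated correlation), while fry gave p = 0.00422 for movement in 1 direction. The values are reads of total RNA at miRNA genes and not mature miRNA. MIR2275c rests on 77 counts in *pam1* and 2 in A344, a ratio of 38.4 with a 95% interval of 10.3 to 322. Whether MIR159 rows share reads was not tested, and how the authors' counting treated reads that match several rows is not given in the sources used here. By edgeR, the MIR408b call was lost without *pam1* replicate 1 (adjusted p = 0.0562) or 2 (0.119), and without A344 replicate 2 (0.0584) or 3 (0.0948). Under DESeq2 its adjusted p was 0.0726, and over all its alternatives the range was 0.000739 to 0.119. Its log2 fold change ranged from 1.14 (without A344 replicate 2) to 2.18 (without A344 replicate 1). The MIR159b call was lost without *pam1* replicate 1 (adjusted p = 0.0778) and under DESeq2 (0.0797), in a range of 0.00224 to 0.0797.

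**Figure D2:**
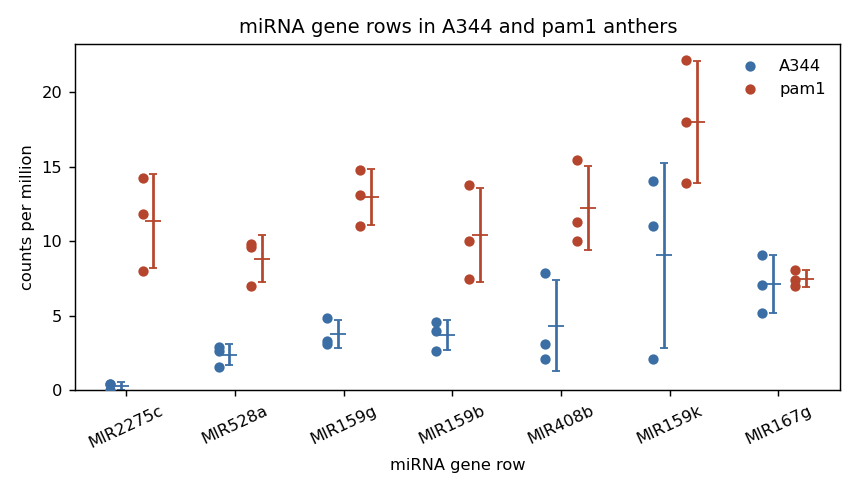
CPM of the 7 tested miRNA genes in the 3 A344 libraries (blue) and the 3 *pam1* libraries (red), 1 point per library, with the mean and SD beside them. MIR2275c stands at 11.3 CPM in *pam1* and 0.285 CPM in A344, while MIR167g is at 7.48 and 7.12 CPM.

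Some rows were near 0 in 1 group. In A344, 150 rows had at most 3 counts over the 3 libraries while reaching at least 5 CPM in *pam1*, and 25 rows showed the reverse. At a minimum of 10 CPM the numbers were 57 and 3. Sequence differences between the lines were not separated from loss of PAM1 as a source of this imbalance. Without *pam1* replicate 3, the numbers were 163 and 90, with the limit of 3 counts then covering 2 *pam1* libraries. With 2 libraries per group and at most 2 counts, 170 to 176 rows were near 0 in A344 and 66 to 73 in *pam1* when *pam1* replicates 1 and 2 were used, and 145 to 161 and 22 to 27 when *pam1* replicate 3 was among them.

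That library lay nearer to A344 than the other *pam1* libraries. In all, 9 rows had no count in *pam1* replicates 1 and 2 and at least 10 CPM in A344, and 9 of 9 had counts in *pam1* replicate 3, at 10.8% to 34.3% of the A344 level (median 16.4%). The same measure had a median of 0 in each A344 library, over 30, 32 and 24 rows, at levels relative to *pam1*. For *pam1* replicates 1 and 2 there were 0 such rows. There a row must have no count in *pam1* replicate 3, so counts in that library keep rows from qualifying. The 0 is therefore no check on *pam1* replicates 1 and 2. At a minimum of 5 CPM in A344, 25 of 26 rows had counts in *pam1* replicate 3, the exception being Zm00001d010482. Correlations of log2 CPM across rows with the A344 libraries were 0.896 to 0.912 for *pam1* replicate 3 and 0.866 to 0.885 for *pam1* replicates 1 and 2 (rows are not independent replicates). Without this library, 2405 rows were changed (1323 higher and 1082 lower), of which 2100 were also changed with it, and MIR2275c, MIR528a, MIR159g, MIR159b and MIR408b were called either way.

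**Figure D3:**
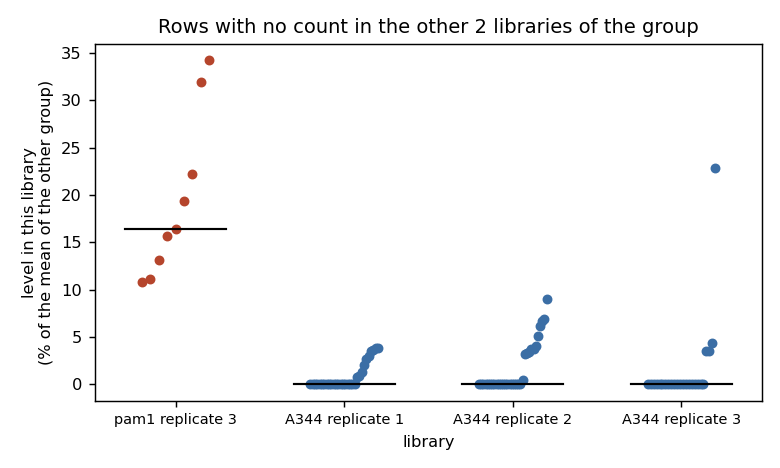
Level of rows that had no count in the other 2 libraries of the same group and at least 10 CPM in the opposite group, as a percentage of the opposite group's mean. Each point is a row and each line a median, at 16.4% for *pam1* replicate 3 and 0 for the 3 A344 libraries.

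Changed rows were unevenly spread along the count table, whose 10 stretches follow chromosomes. In windows of 200 tested rows, 11 of 92 windows, in 5 stretches, held an excess of changed rows (one-sided Fisher's exact test, adjusted p under 0.05). Inside them 24.5% of rows were changed and elsewhere 13.5%. The share of changed rows that were higher in *pam1* was 51.9% inside these windows and 56.2% elsewhere. By stretch, 11.6% to 19.5% of rows changed, with the highest share in stretch 3. Stretches are numbered in table order, not by chromosome number. The number of windows was 7 under DESeq2 and also without A344 replicate 3, and 5 with an absolute log2 fold change of at least 1.

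**Figure D4:**
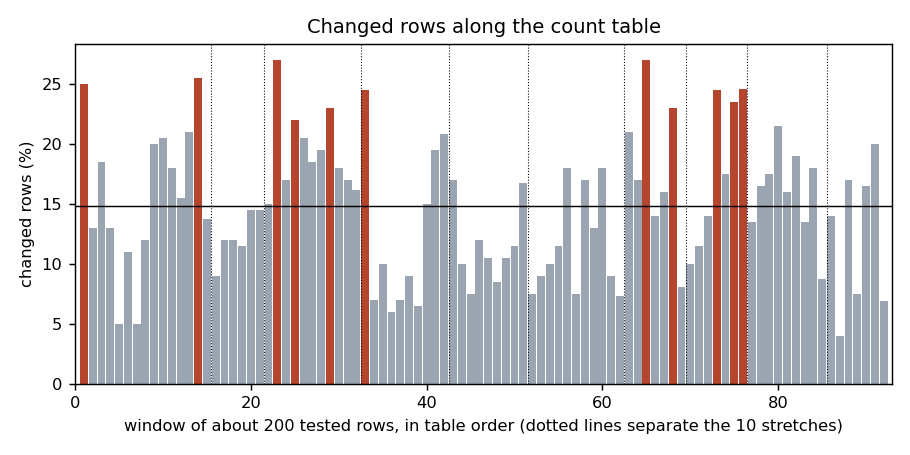
Percentage of changed rows in each window of about 200 tested rows, in table order, with dotted lines between the 10 stretches and a horizontal line at 14.9%. The 11 windows with an excess are red, and shares run from 4% to 27%.

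The authors' deposited table called 1895 rows, 1064 higher in *pam1* and 831 higher in A344. Of these, 1675 were also called by edgeR, and 100% of them had the same direction. Both sets of calls come from the same counts, so this is not an independent check. A further 209 of the rows called in the authors' deposited table had too few counts to be tested by edgeR. For MIR2275c the authors' deposited table gives a log2 value of −5.20 (A344 over *pam1*) with an adjusted p of 0.000215. Its adjusted p was 0.0349 for MIR528a and 0.00972 for MIR159g. MIR159b (0.0797) and MIR408b (0.0726) were not called in it.

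Anti-PAM1 RIP from A344 anthers gave 711 peaks in the combined list. Of these, 702 lay on chromosomes 1 to 10, 3 on the mitochondrial genome and 6 on unplaced contigs. Chromosome 1 held the most, 113 peaks, and chromosome 10 the fewest, 43. The median fold enrichment was 3.94 (1.39 to 9.69), and 531 peaks had a −log10 q of at least 3.

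The highest −log10 q values belonged to a pair of peaks on chromosome 9 of B73 v4, at 20238247 to 20238435 (27.9, fold enrichment 2.64) and 20383652 to 20383825 (23.5, fold enrichment 2.56). Next came chromosome 3 at 146709527 to 146709700 (15.2, fold 3.42), chromosome 9 at 148186620 to 148186929 (13.9, fold 7.31) and chromosome 10 at 116550262 to 116550479 (12.5, fold 7.89). The highest fold enrichment in the list, 9.69, was on chromosome 2 at 29538322 to 29538514. The mitochondrial peaks, at 400420 to 400746, 402983 to 403183 and 419801 to 421026, were the 3 peaks with a fold enrichment under 2 (1.39 to 1.71). Annotation of B73 v4 was not used here, so the genes under these peaks are not named.

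Peaks were narrow: the median width was 170 bp, which was also the smallest, and 452 peaks had it. A single combination of values (fold enrichment 3.94, −log10 q 3.88) was shared by 201 peaks, and the 5 most common combinations covered 427 of the 711. Of the nuclear peaks, 57 lay within 5000 bp of another peak. All peak values are the authors' own, from combined samples, and the list gives no strand.

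**Figure D5:**
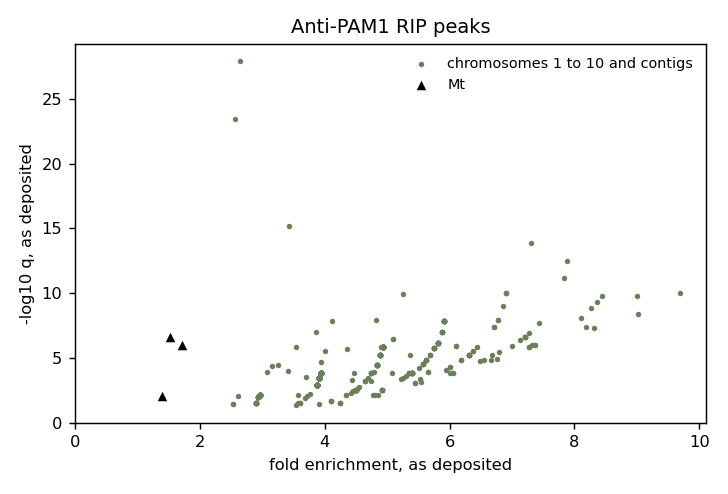
Fold enrichment (horizontal axis) and −log10 q (vertical axis) of the 711 peaks as deposited, with the 3 mitochondrial peaks as triangles. Many points coincide, since 201 peaks share a fold enrichment of 3.94 and a −log10 q of 3.88.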

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

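The miRNA genes as a group, MIR159g, MIR159k, MIR167g, table windows and rows near 0 were chosen after the data were seen; the numbers of changed, higher and lower rows and of peaks were fixed beforehand. With no low-count filter 2305 rows were higher, of more rows tested (4073 changed, 1768 lower). DESeq2 called 1895 rows, 3 miRNA genes higher and 7 windows; the cause was not tested. At adjusted p under 0.01 there were 1432 changed rows (836 higher, 596 lower) and 3 miRNA genes. With an absolute log2 fold change of at least 1 there were 1359 (851 and 508) and 5 windows. These last limits call fewer by construction. Leaving out 1 library gave 1768 to 2917 changed rows, 723 to 1350 lower rows, 3 to 5 miRNA genes and 7 to 14 windows, with fewer samples in each fit. The lowest values came without *pam1* replicate 1 (1768 changed, 728 lower, 3 miRNA genes), *pam1* replicate 2 (723 lower) and A344 replicate 3 (7 windows). For rows near 0 in A344 and in *pam1*, at most 1 count gave 94 and 4, at least 10 CPM gave 57 and 3, and leaving out *pam1* replicate 3 gave 90 for the second, partly by construction since the limit of 3 counts then covers fewer libraries. Other scalings, the 1 CPM filter and limma voom kept every count of changed rows, miRNA genes and windows within 1.5 times. Library size alone gave 60.1% higher calls against 55.1%.

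With the replicate number as a block, 3352 rows changed (1796 higher, 1556 lower), 2717 of them shared with the unpaired fit. Of the 11 named rows, the block changed only the MIR159k call. Over 143 alternative values of named rows, 134 stayed on their side of the threshold, 7 lost a call, 2 gained one and 0 reversed. Stricter limits left 531 peaks (−log10 q of at least 3) and 484 (fold enrichment of at least the median). Alternatives chosen beforehand for gene lists, genes with a peak, their overlap and fold change, and 10 Mb windows were not run, since no names or matching coordinates were used. Depth limits rows near the filter, and 147 miRNA genes had too few counts for a test.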

Other observations

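The tests on *pam1* replicate 3, on MIR2275c and on regions longer than a window were chosen only after those results were seen, as were the table windows, the miRNA families, MIR398a and the GRMZM rows.

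In 11 miRNA families with at least 20 pooled counts, 4 had every *pam1* library above every A344 library: MIR159 with a *pam1* to A344 ratio of 2.24 (95% interval 1.82 to 2.76), MIR2275 with 6.55 (3.71 to 12.4), MIR408 with 2.76 (1.80 to 4.34) and MIR528 with 3.20 (1.89 to 5.67). These ratios largely repeat rows already given: MIR408 is the row MIR408b alone, whose call was lost in 5 of the alternatives, MIR528a holds 59 of the 61 MIR528 counts in *pam1*, MIR2275c holds 77 of the 92 MIR2275 counts, and MIR159k, MIR159g and MIR159b hold 117, 86 and 69 of the 303 MIR159 counts. MIR398, which like MIR408 and MIR528 belongs to the copper-responsive miRNAs of plants, had a ratio of 2.19 (1.27 to 3.93), with libraries of the groups overlapping. Its member MIR398a had 41 counts in *pam1* and 17 in A344. MIR167 had a ratio of 1.07 (0.726 to 1.58). MIR2118, the trigger of an earlier class of anther phased small RNAs, had 8 counts in *pam1* and 14 in A344 (0.569, 0.207 to 1.45), too few to show a difference. The intervals cover counting error only.

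Of the 174 GRMZM rows, 115 had a count, and among the tested ones more fell than rose. Of 61 tested, 11 fell and 2 rose by edgeR (12 and 3 adjusted over the list alone), with a median log2 fold change of −0.27 and a camera adjusted p of 0.000324. The call was lost with an estimated correlation (adjusted p = 0.341 with an estimated correlation), and fry gave p = 0.0880 for 1 direction and 0.000336 for either. All GRMZM rows together took 1.57 ± 0.120% of counts in *pam1* and 1.84 ± 0.254% in A344 (SD, n = 3 each; exact permutation p = 0.2, and 0.25 with signs flipped within replicate numbers).

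Of the 10 ways to split the 6 libraries into groups of 3, 1 gave as many changed rows as the real grouping, namely itself with 2748, and the highest other value was 0, also among the 3 other splits that part all 3 pairs. Every other split mixes *pam1* and A344 libraries, which adds the group difference to the spread and keeps calls low. Values of 0 there do not show how many calls a grouping of like libraries would give. With 10 splits no share under 0.05 can be reached.

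MIR2275c rose by more than any other tested miRNA gene. Whether all MIR2275 genes shifted together, as a difference in stage might give, stays open. The other MIR2275 rows had 15 counts in *pam1* and 12 in A344, a ratio of 1.25 (95% interval 0.544 to 2.91). This interval lies below that of MIR2275c, 10.3 to 322, so a shift of equal size was not seen in their pooled counts. Both intervals cover counting error only, and each of these other rows had too few counts for a test. In *pam1* replicates 1 to 3 the family had 24, 41 and 27 counts and MIR2275c had 24, 37 and 16. Most counts of the other rows in *pam1* thus came from replicate 3. Reads divided among copies would need about 75 more counts in A344, where the other rows hold 12. Of its 100 nearest tested rows 13 changed, an odds ratio of 0.855 (95% interval 0.437 to 1.54), below the 2.08 of windows with an excess. Loss of PAM1, a sequence difference between the lines at this gene, and strand handling of the counts stay open, untested.

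*pam1* replicate 3 may hold A344-type RNA. Rows silent in the other *pam1* libraries stood at a median of 16.4% of the A344 level in it, and rows silent in A344 at a median of 70.4% of the level in *pam1* replicates 1 and 2. Low depth is argued against: with all libraries thinned to 1918457 counts, its correlations with A344 libraries across rows were 0.895 or more, and those of *pam1* replicates 1 and 2 were 0.883 or less. A344 background confined to a few stretches of the count table is argued against. Counts were seen in 9 of 9 rows of at least 10 CPM, from 5 stretches. They were also seen in 25 of 26 rows of at least 5 CPM, from 9 stretches. Only Zm00001d010482 had none, and at the pooled share of 21.4% counting error alone gives 1.02 such rows. Smaller blocks of A344 background spread over many stretches stay open, since they were not mapped. A wild-type or heterozygous plant in the pool and RNA carried over between tubes were not separated, and no biological explanation was tested.

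Changed rows may be grouped by chromosome region. Differences in expression and so in power are argued against: permuting calls within expression deciles gave at most 2 windows with an excess, against 11. Neighbouring changed rows shared a direction in 54.6% of cases, above the 52.4% reached at the upper end of permuted signs, and shares of changed rows in neighbouring windows correlated at r = 0.324 across 82 pairs of windows (upper end of permutations 0.201), which is consistent with regions longer than a window. Whether these are blocks of another background carried with the mutation cannot be told apart from shared regulation: rows near 0 in 1 group were 3.40% of the changed rows in such windows and 4.76% elsewhere (odds ratio 0.703, 95% interval 0.403 to 1.17), which leaves both open. This split by window cannot detect differences between the lines that are spread over all windows. Loss of PAM1 itself stays open, untested.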
